A study of Mus musculus with 6 samples.

How the data were processed

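Gene expression was measured in mandibular arches of mouse embryos at stage E10.5 on Affymetrix Mouse Genome 430 2.0 arrays, 3 labelled wild type and 3 labelled Tbx1 null. Per the labels' protocols, tissue was homogenized, total RNA was isolated on columns, and labelled cDNA was amplified from 100 ng of total RNA. The deposited values are log2 expression per probe set; per the submitters' processing notes they were made with GCRMA, which corrects the background by probe sequence, normalizes between arrays and summarizes the probes of a set, and its version is not given in the sources used here. That the values are on a log2 scale was read from the values, which run from 1.95 to 15.11 with nearly equal quantiles on every array. Quantile normalization holds the overall distribution equal, so a shift of most genes in one direction would be removed, and GCRMA compresses differences near the background. No scanner files were used here.

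The table held 45101 probe sets, 64 of them controls. The platform annotation named 1 gene for 34958 probe sets, several for 932 and none used here for 9160, and 34754 of the 34958 were matched by gene ID to the reference table of mouse genes, which changed 0 symbols. Only probe sets with 1 gene symbol were used for genes, which gave 18194 genes, and each gene was represented by its probe set with the highest mean over the 6 arrays. Genes were kept when that probe set exceeded 4 on the log2 scale on at least 3 arrays, which left 16074 genes and set aside 2120. Probe sets of 1 gene can disagree: for Lrrn1 the brightest set fell by 1.55 and the others by 0.15 and 0.33, with values of 4.05 or below, and for Tcf21 the second set differed by 0.19 at values of 2.94 or below. Sets that were not dim also disagreed: the other sets of Chrdl1 fell by 0.18, 0.33 and 0.88, against 1.36 on the brightest, and the set with the smallest fall averaged 6.50 on the wild-type arrays. The other sets of Ndrg1 rose by 0.29 to 1.67, those of Pfkp by 0.34 and 0.59, that of Adm by 2.53 and that of Stmn2 by 0.22, and those of Ttr fell by 0.69 to 2.05. No genome coordinates are printed, since no build is named by the files.

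The comparison was fitted with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with an intensity trend on genotype alone, and adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, adjusted by Benjamini-Hochberg over 27 lists; 28 lists were fixed, and the sex-linked genes served as a sample check. With an estimated correlation, camera also takes its degrees of freedom from the residuals of the few arrays. Its p-values are then larger whatever the correlation, and larger still with an array left out or with a block. Fry tests whether the genes of a list move on balance in 1 direction, and does not compare them with other genes. Counts adjusted over the list alone use Benjamini-Hochberg over the tested members. Tbx1 was also tested by a two-sided exact permutation test and, paired by replicate number, by one over all changes of sign, the latter chosen after seeing the data. The design, the lists and the rule for named genes were fixed before the data were examined.

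The rule named Tbx1, the genes past the threshold with non-overlapping groups or, where fewer than 5 passed in a direction, the 5 with the smallest p there, up to 4 members of each list with the smallest p, and 11 genes fixed by name, of which 10 were tested. It gave 121 genes, and the text prints part of them, that part being chosen after their values were seen. Genes outside the rule are said to be named after their values were seen.

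No pair of the 6 arrays held identical values: the SD of the difference between 2 arrays of a genotype lay between 0.247 and 0.411 over all probe sets. The labels number replicates 1 to 3 in both genotypes without saying what a number shares. Deviations from the genotype means correlated at 0.261, 0.13 and 0.135 for arrays of the same number and between -0.195 and 0.065 otherwise. Deviations within a genotype balance out by construction, which forces part of this contrast, and 3 arrays per genotype leave few possible pairings. On the data alone the numbers were therefore treated as a possible pairing of the samples. The mean of the hybridization control spikes was likewise highest on replicate 2 of both genotypes, 12.98 and 12.80, against 12.50 to 12.56 on the others. Blocked values stand beside results whose call they change.

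Signal over background limits what an array can show, so a value near 4 is a weak basis for a fold change. On 20 simulated data sets of 16074 genes with 200 changed genes each, the limma step called 80.7% of genes changed by 1 and 97.2% of genes changed by 2 on the log2 scale, and 4.44% of its calls were unchanged genes. A list shifted by 0.5 was called in all 20, and 0.05 unshifted lists per data set were called on average. Each gene was drawn on its own, without correlation between genes, pairing or an array that stood apart. With 200 changed genes the adjusted threshold is also easier to reach than in the real fit, which called 6 genes. These shares therefore do not give the power or the list errors of the real fit.

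Alternatives chosen beforehand were another normalization, other filters and a floor for dim values, other moderation of the spread, other ways of choosing a gene's probe set, array weights, the replicate block, other thresholds, probe sets tested one by one, and leaving out each array in turn. Tests without labelled-null replicate 3 and with the block, both with an estimated correlation, were chosen after seeing the data, as were list medians and counts over the list alone with each array left out. Figures were drawn with matplotlib.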

Results

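Gene expression was measured in the mandibular arch of mouse embryos at stage E10.5, the tissue from which the lower jaw and its muscles form, on 6 Affymetrix Mouse Genome 430 2.0 arrays. 3 arrays were labelled wild type and 3 were labelled homozygous null for Tbx1, which encodes a T-box transcription factor needed for pharyngeal development. The comparison asks which transcripts differ in this tissue when Tbx1 is lost. Arches of 3 embryos per genotype were pooled, and the description does not settle whether each array carried a pool of its own, so the p-values measure only the spread between these samples. The arrays labelled null did not carry 1 common RNA: Xist, transcribed from the inactive X chromosome, read 5.60 (log2) on labelled-null replicate 2, 11.55 on labelled-null replicate 1 and 10.60 on labelled-null replicate 3, and its 2 other probe sets were likewise low on labelled-null replicate 2 alone (4.07 and 4.47, against 8.36 or above elsewhere). On the wild-type arrays Xist ranged from 10.43 on replicate 1 to 11.53 on replicate 3, and the Y-linked genes Eif2s3y (10.03 to 10.63), Kdm5d (8.06 to 8.84) and Uty (6.07 to 7.35) were highest on replicate 1 and lowest on replicate 3. The Y-linked genes were present on the labelled-null arrays too, with Eif2s3y between 10.15 and 10.94. Array medians lay between 6.08 and 6.15 on the log2 scale, and the number of arrays limits the precision of every value.

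Tbx1 transcript was not lower on the arrays labelled null. Its 1 probe set averaged 7.06 ± 0.22 (log2, SD, n = 3) on the wild-type arrays and 7.46 ± 0.15 (SD, n = 3) on the labelled-null arrays. The difference of 0.41 (SE 0.14) gave p = 0.20 in a two-sided exact permutation test, in which 3 arrays against 3 cannot go below 0.10. In limma the unadjusted p was 0.0205 and the adjusted p over all genes 1.00, and 0.0144 and 0.951 with the replicate block. Taken by replicate number, the labelled-null array was higher in all 3 pairs, by 0.66, 0.19 and 0.38, and a two-sided exact paired permutation test, chosen after seeing the data, gave p = 0.25, the smallest that 3 pairs allow. The part of the gene that was disrupted is not given in the sources used here, so this probe set does not check the labels, and directions below follow the genotype as labelled.

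Of the genes tested, 6 passed the threshold, and 2 of them, Myf5 and Tcf21, are regulators of the muscle lineage in the arch core. Myf5, a determination factor of skeletal muscle, fell 5.04-fold (log2 change -2.33, SE 0.27, n = 3 per genotype), and Tcf21, a basic helix-loop-helix factor of the branchial muscle lineage, fell 2.90-fold (log2 -1.53, SE 0.13). Lrrn1, a leucine-rich repeat membrane protein, fell 2.93-fold (log2 -1.55, SE 0.10), and Chrdl1, a secreted BMP antagonist, fell 2.56-fold (log2 -1.36, SE 0.15) on its brightest probe set and by 0.18, 0.33 and 0.88 (log2) on its other sets. Bhlhe40, a transcriptional repressor, rose 5.58-fold (log2 2.48, SE 0.26), and Ier3, an early response gene, rose 3.52-fold (log2 1.82, SE 0.21). On each of these 6 genes all 3 labelled-null arrays lay outside the range of the wild-type arrays.

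These 6 genes, 2 higher and 4 lower, were those with an adjusted p under 0.05 among 16074 genes tested in limma with Benjamini-Hochberg adjustment. Their adjusted p-values were 0.00340 for Lrrn1, 0.0184 for Tcf21, 0.0461 for Bhlhe40 and 0.0493 for Chrdl1, Ier3 and Myf5. Bhlhe40, Chrdl1, Ier3 and Myf5 did not pass without the filter, with values under 4 raised to 4 or without the intensity trend, and none of the 6 passed with the mean of a gene's probe sets (246 genes higher and 231 lower at an unadjusted p under 0.05 in limma). Ier3 did not pass after a further quantile normalization or with arrays centred on their medians, nor Myf5 with array weights. At an unadjusted p under 0.05 there were 237 higher and 193 lower genes. These 430 of 16074 genes are a smaller share than the 0.05 expected if no gene differed, so such counts are no evidence of a difference. Groups did not overlap for 6.43% of the genes, where chance gives 10% for 3 against 3. Of the genes next in rank, which missed the threshold, Ndrg1 differed by 1.90 (SE 0.23, adjusted p = 0.0637), Plekha2 by 1.53 (SE 0.21, adjusted p = 0.113), Upp1 by 1.31 (SE 0.20, adjusted p = 0.205) and Lhx2 by -1.71 (SE 0.23, adjusted p = 0.113). With the replicate number as a block, 4 genes were higher and 6 lower: Chrdl1 passed no longer (adjusted p = 0.0590), the other 5 did, and Ndrg1, Adm, Tnnt1, Ttr and Pcdh8 joined them, Pcdh8 being named after its values were seen.

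**Figure D1:**
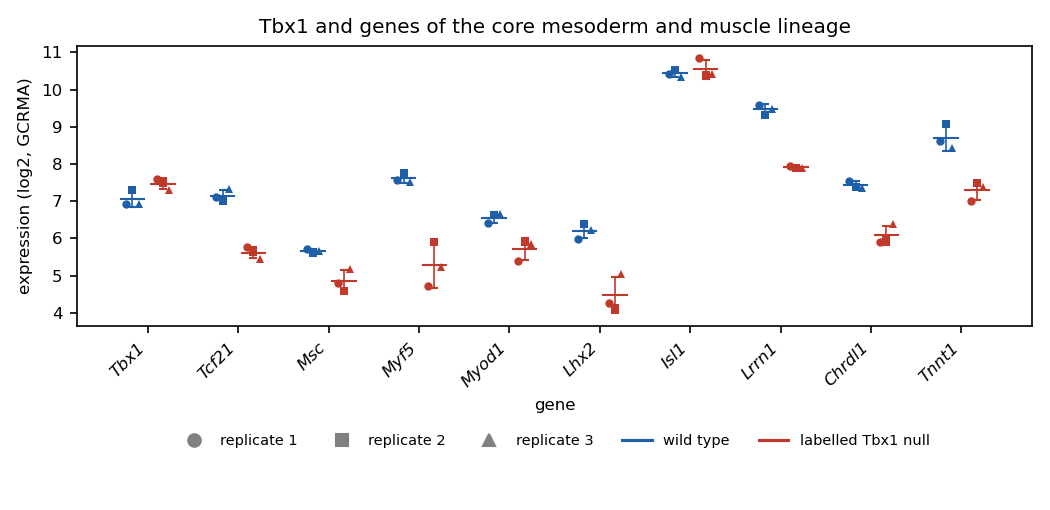
Expression (log2, GCRMA) of 10 genes on each array. Points are the 3 replicates of each labelled genotype, horizontal lines the means and vertical bars 1 SD. Tcf21, Msc, Myf5, Myod1, Lhx2, Lrrn1, Chrdl1 and Tnnt1 are lower on all 3 labelled-null arrays than on any wild-type array, and Tbx1 and Isl1 overlap.

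1 array stood apart from the rest. Labelled-null replicate 3 held 249 genes more than 1 above the mean of the other arrays on the log2 scale, against 6 to 32 on each of the others, and the leading principal component, with 48.8% of the variance, set it apart. The genes furthest above were placental prolactin family members and other placental transcripts, named after their values were seen: Prl7a1 read 13.28 against a mean of 3.98 on the other arrays, Prl4a1 13.19 against 5.75, and Cyp11a1, a steroidogenic enzyme, 11.80 against 4.61. Without this array 14 genes passed higher and 8 lower, and all 6 genes above were among them. Leaving out wild-type replicate 1 left 0 higher and 1 lower gene, wild-type replicate 2 left 0 and 1, in both cases Lrrn1, and wild-type replicate 3 left 0 and 0, with 204, 226 and 286 genes higher and 248, 135 and 218 lower at an unadjusted p under 0.05 in limma. Without labelled-null replicate 1 there were 3 higher and 4 lower, and without labelled-null replicate 2 there were 4 and 3; of the 6 genes Chrdl1 did not pass without either, nor Bhlhe40 without labelled-null replicate 2.

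**Figure D2:**
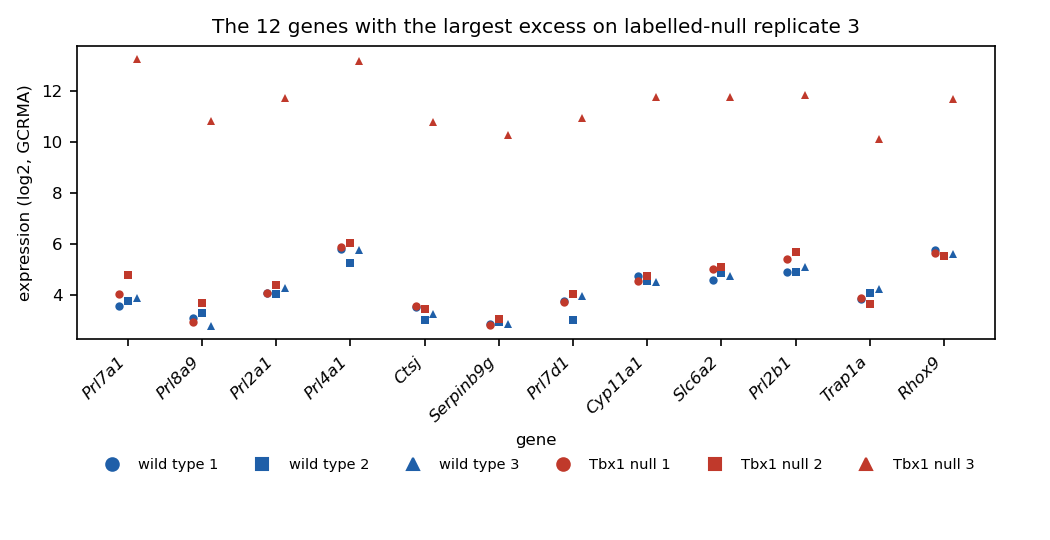
Expression (log2, GCRMA) on each array of the 12 genes with the largest excess on labelled-null replicate 3 over the mean of the other arrays. Each point is 1 array, with colour for the labelled genotype and shape for the replicate. Labelled-null replicate 3 lies at 10.11 or above for all 12 genes, and the other arrays at 6.04 or below.

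Among the core mesoderm and myogenic regulators fixed before the data were examined, 7 of 17 tested genes fell when adjusted over the list alone, 0 rose and 10 did not pass. Over all genes, 2 of the list passed, Tcf21 and Myf5. Lhx2, a LIM homeodomain factor, was 3.28-fold lower (log2 -1.71, SE 0.23), Myod1, a muscle determination factor, 1.80-fold lower (log2 -0.84, SE 0.16), and Msc, or musculin, 1.76-fold lower (log2 -0.81, SE 0.16). Myog and Pax7, named after their values were seen, were the remaining members to fall, from means of 5.37 to 4.78 and of 4.82 to 4.07. The labelled-null means of Lhx2 and Msc were 4.48 and 4.85. These changes thus reach towards the low end of the scale, a weak basis for their size. Isl1 differed by 0.12 (SE 0.13), not past the threshold, and by -0.03 without labelled-null replicate 1 to 0.20 without labelled-null replicate 2. In all, 12 members had lower and 5 higher means on the labelled-null arrays. Adjusted over the list alone, 8 members fell without labelled-null replicate 3, and 6 without labelled-null replicate 1 or wild-type replicate 2. The list as a whole was lower in camera (adjusted p = 2.0e-13, Benjamini-Hochberg over 27 lists), adjusted p = 0.0312 with an estimated correlation. With that estimate its adjusted p was 0.114 without labelled-null replicate 3 and 0.294 with the replicate block.

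Genes of skeletal muscle structure were lower as a list, with a median log2 change of -0.07 over 20 genes (-0.12 without wild-type replicate 1, -0.10 without labelled-null replicate 1 and -0.05 without labelled-null replicate 2). Camera gave an adjusted p of 0.00498, but adjusted p = 0.177 with an estimated correlation. 1 of them fell when adjusted over the list alone and 0 over all genes in limma (2 lower and 1 higher at an unadjusted p under 0.05): Tnnt1, a slow-muscle troponin T, was 2.65-fold lower (log2 -1.41, SE 0.19), adjusted p over all genes = 0.113, and 0.0361 with the replicate block, under which 2 of the list fell. Myl1 differed by -0.44 (SE 0.15) and Mylpf by -0.37 (SE 0.17), both myosin light chains, and Unc45b, a myosin chaperone, by 0.39 (SE 0.15), none past the threshold. Mylpf differed by -0.19 without wild-type replicate 2 and Unc45b by 0.26 without wild-type replicate 3.

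Genes of hypoxia and glycolysis were higher as a list on the arrays labelled null (median log2 change 0.54). Camera gave an adjusted p of 8.6e-37, but adjusted p = 0.127 with an estimated correlation, the correlation between members being estimated at 0.48. With that estimate the list did not pass without labelled-null replicate 3 (0.174) or with the replicate block (0.294) either. All 22 tested genes had higher means, and 17 rose when adjusted over the list alone. Over all genes 0 passed in limma, with 17 at an unadjusted p under 0.05, and for 14 the 3 labelled-null arrays all lay above the wild-type arrays. Ndrg1, a hypoxia-inducible gene, was 3.73-fold higher (log2 1.90, SE 0.23), Adm, which encodes the vasodilator adrenomedullin, 9.16-fold (log2 3.20, SE 0.60), Pfkp, a phosphofructokinase, 2.62-fold (log2 1.39, SE 0.23), and P4ha2, a collagen prolyl hydroxylase, 1.66-fold (log2 0.74, SE 0.14). Without labelled-null replicate 3 the median was 0.74 and 20 genes rose when adjusted over the list alone, and Adm, whose highest value of 11.66 was on this array, differed by 2.51. Over all genes Ndrg1 (adjusted p = 0.0270), Pfkp (0.0235) and Slc2a3 (0.0235), the last named after its values were seen, passed in limma without that array. The median was 0.35 without labelled-null replicate 1, and leaving out any array other than labelled-null replicate 3 left 13 to 16 genes over the list alone. With the replicate block 19 rose over the list alone, and Ndrg1 (adjusted p = 0.0478) and Adm (adjusted p = 0.0431) passed over all genes in limma.

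Immediate early genes, which respond within minutes to stimuli and handling, were higher as a list (median log2 change 0.24, 18 genes). Camera gave an adjusted p of 1.3e-11, but adjusted p = 0.127 with an estimated correlation. 3 rose when adjusted over the list alone, Ier3, Atf3 (1.60-fold, log2 0.68, SE 0.14) and Junb (1.31-fold, log2 0.39, SE 0.11), and 1 over all genes, Ier3. Klf6 differed by 0.40 (SE 0.12) and did not pass. Adjusted over the list alone, 7 genes rose without labelled-null replicate 2, 1 without labelled-null replicate 1 or wild-type replicate 2, and 2 without each of the other arrays.

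**Figure D3:**
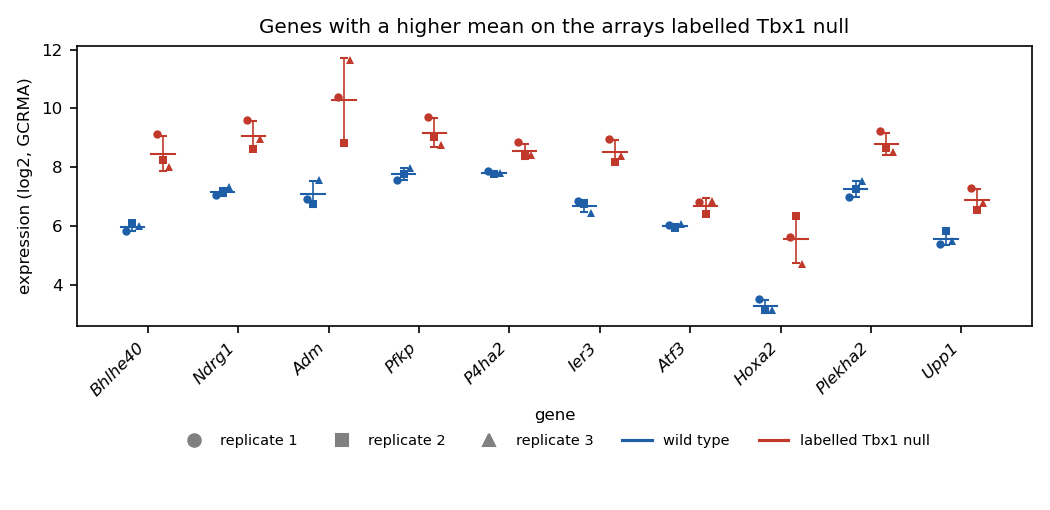
Expression (log2, GCRMA) of 10 genes on each array. Points are the 3 replicates of each labelled genotype, horizontal lines the means and vertical bars 1 SD. On all 10 genes the labelled-null arrays lie above the wild-type arrays, and Adm is highest on labelled-null replicate 3, at 11.66.

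Hox genes, which are not expressed in the mandibular arch of normal embryos, were higher as a list (median log2 change 0.16, 13 genes). Camera gave an adjusted p of 0.00302, but adjusted p = 0.127 with an estimated correlation. In the list 1 gene rose when adjusted over the list alone and 0 over all genes in limma (1 higher at an unadjusted p under 0.05). That gene was Hoxa2, a selector of the second arch, at 3.28 ± 0.22 (log2, SD, n = 3) on the wild-type arrays and 5.57 ± 0.82 (SD, n = 3) on the labelled-null arrays, with all wild-type values under the level of 4 used as the filter. Its adjusted p in limma was 0.205 over all genes and 0.00347 without labelled-null replicate 3. Other members read higher on the wild-type arrays, with means of 6.85 for Hoxc8 and 6.27 for Hoxc6, both named after their values were seen. Whether these readings reflect Hox transcript or background signal of the probe sets was not tested. Hoxa3 differed by 0.19 (SE 0.12) and Hoxb2 by 0.17 (SE 0.12), neither past the threshold, Hoxa3 by 0.12 without wild-type replicate 2 and Hoxb2 by 0.07 without wild-type replicate 3. Without labelled-null replicate 3, 2 genes rose when adjusted over the list alone, and without labelled-null replicate 2 the list median was 0.09.

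Patterning genes of the jaw mesenchyme did not pass as a list (adjusted p = 0.140 in camera, 27 genes), and 2 fell when adjusted over the list alone with 0 over all genes in limma (2 lower and 1 higher at an unadjusted p under 0.05). Foxd1, a forkhead factor, was 1.51-fold lower (log2 -0.59, SE 0.11) and Gbx2, a homeobox factor, 1.81-fold lower (log2 -0.86, SE 0.18). Dlx5 differed by -0.20 (SE 0.16) and Hand2, a ventral identity factor, by 0.12 (SE 0.11), and neither passed. With 1 array left out Dlx5 ranged from -0.30 without wild-type replicate 3 to -0.02 without wild-type replicate 1, and Hand2 from 0.02 without wild-type replicate 1 to 0.19 without labelled-null replicate 3. Adjusted over the list alone, 3 members fell without labelled-null replicate 3, and 0 without wild-type replicate 1 or 2 in limma. Chondrogenic genes gave an adjusted p of 0.320 over 13 genes, with a median of 0.04 but a mean of -0.04 and a lower direction in camera.

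Signalling genes differed little: 0 passed in limma adjusted over the list alone or over all genes, with 4 BMP, 2 Hedgehog, 1 retinoic acid and 0 FGF, Wnt and Notch genes at an unadjusted p under 0.05. BMP ligands and targets were higher (median 0.12, 17 genes, camera adjusted p = 7.6e-04), with Smad6 at 0.33 (SE 0.10) and Smad7 at 0.27 (SE 0.09), both inhibitory Smads, and Bmper at -0.59 (SE 0.21), but adjusted p = 0.127 with an estimated correlation; the median was 0.08 without labelled-null replicate 1, and 1 gene fell over the list alone without wild-type replicate 3. Hedgehog genes were lower (median -0.06, 12 genes, adjusted p = 0.0351), with the ligand Shh at -0.43 (SE 0.19; -0.67 without labelled-null replicate 1) and its target Hhip at -0.42 (SE 0.12), and adjusted p = 0.177 with an estimated correlation; the preset test gave 0.376 without labelled-null replicate 3 and 0.0625, 0.0704 and 0.120 without wild-type replicates 1, 2 and 3. The Hedgehog median was -0.13 without wild-type replicate 1 and -0.12 without labelled-null replicate 2, and 1 gene fell over the list alone without labelled-null replicate 1. The FGF list did not pass (adjusted p = 0.498, 17 genes), with Fgf8 at 0.11 (SE 0.13) and Fgf10 at 0.20 (SE 0.14). With 1 array left out Fgf8 ranged from 0.02 without labelled-null replicate 3 to 0.21 without labelled-null replicate 1, and Fgf10 from 0.12 without labelled-null replicate 1 to 0.32 without wild-type replicate 1. Retinoic acid (0.138), Wnt (0.681) and Notch (0.693) did not pass in adjusted p either, but the retinoic acid pathway was lower without wild-type replicate 3 (0.00276) and without labelled-null replicate 2 (0.0398), and 1 of its genes fell over the list alone without wild-type replicate 1. These are preset tests, and with an estimated correlation and all arrays the retinoic acid list had an adjusted p of 0.564 in camera. Aldh1a1, a retinaldehyde dehydrogenase, differed by -0.78 (SE 0.23). With the replicate block 1 gene each of the retinoic acid, oral ectoderm and pharyngeal endoderm lists fell when adjusted over the list alone.

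Markers of other cell types were also compared, since a dissected arch holds more than mesenchyme. Erythroid genes were lower, all 13 of them in mean (median -0.18, camera adjusted p = 5.1e-08), with Car2 at -0.28 (SE 0.10) and Nfe2 at -0.35 (SE 0.12), and 0 passed adjusted over the list alone in limma (3 at an unadjusted p under 0.05); adjusted p = 0.127 with an estimated correlation. Endothelial genes were higher (median 0.14, 21 genes, adjusted p = 1.0e-04), with Sox17 at 0.64 (SE 0.20) and Flt1, a VEGF receptor, at 0.71 (SE 0.25; 0.42 without labelled-null replicate 1). Of these 0 passed adjusted over the list alone in limma (3 at an unadjusted p under 0.05), the median was 0.08 without labelled-null replicate 3, and the adjusted p was 0.127 with an estimated correlation. Neuronal genes were higher (median 0.07, 17 genes, adjusted p = 0.0105), with 1 gene rising over the list alone, Stmn2, a microtubule regulator (1.87-fold, log2 0.90, SE 0.17), and Pou4f1 at 0.34 (SE 0.11), and adjusted p = 0.129 with an estimated correlation; 2 genes rose over the list alone without labelled-null replicate 3, with a median of 0.03. The preset test of neurons gave 0.0505 without wild-type replicate 2 and 0.184 without labelled-null replicate 2. General epithelial genes were higher (median 0.07, 20 genes, adjusted p = 0.00373), but adjusted p = 0.255 with an estimated correlation. Krt18 and Krt19, simple-epithelium keratins, differed by 0.80 (SE 0.34) and 1.13 (SE 0.48), with Krt19 at 11.65 on labelled-null replicate 3 and 9.58 and 9.62 on the other labelled-null arrays. Without that array Krt18 differed by 0.31 and Krt19 by 0.45. Of the general epithelium list 0 passed adjusted over the list alone in limma (3 at an unadjusted p under 0.05), and its adjusted p was 0.326 without wild-type replicate 3; its median was 0.11 without wild-type replicate 2.

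Of the other lists, extracellular matrix genes were higher (median 0.14, 26 genes, adjusted p = 5.8e-04) and proliferation genes lower (median -0.05, 25 genes, adjusted p = 0.00302), each with 0 genes past the threshold adjusted over the list alone or at an unadjusted p under 0.05 in limma, and adjusted p = 0.253 with an estimated correlation. Cardiac markers were higher (median 0.09, 16 genes, adjusted p = 0.0432), but adjusted p = 0.215 with an estimated correlation. Myl7 differed by 0.36 (SE 0.16) and Myl2 by -0.36 (SE 0.15), and by 0.23 and -0.24 without labelled-null replicate 2. The largest rises of the cardiac list, Hand1 at 0.42 (SE 0.25) and Gata4 at 0.38 (SE 0.29), were 0.11 and 0.04 without labelled-null replicate 3. The preset test of extracellular matrix gave 0.130 without wild-type replicate 3 and 0.0760 without labelled-null replicate 2, with medians of 0.05 and 0.07. For proliferation it gave 0.0521 without wild-type replicate 1 and 0.155 without labelled-null replicate 3 (medians -0.03 and -0.03), and the median was -0.08 without wild-type replicate 3. Cardiac markers did not pass without labelled-null replicate 3 (0.433, median 0.03), labelled-null replicate 2 (0.0587) or wild-type replicate 1, 2 or 3 (0.126, 0.0822 and 0.0601). Macrophages (0.180 with all arrays) passed at 3.9e-04 without labelled-null replicate 3 and at 0.0138 without wild-type replicate 3, where 1 gene fell over the list alone, and genes of the Tbx1 neighbourhood (0.145 with all arrays) at 0.00438 without labelled-null replicate 3. With an estimated correlation and without that array neither passed (0.405 and 0.445). Oral and surface ectoderm (0.127), pharyngeal endoderm (0.473), lymphatic endothelium (0.180), neural crest glia (0.426) and p53 targets (0.0570) did not pass with all arrays. Oral and surface ectoderm passed without wild-type replicate 3 (0.0120), pharyngeal endoderm without labelled-null replicate 1 (0.0112), and p53 targets without wild-type replicate 1 (0.0158) and labelled-null replicate 2 (0.0398). These are preset tests, and with an estimated correlation and all arrays the adjusted p-values in camera were 0.314, 0.606 and 0.253, in that order of lists. Adjusted over the list alone, 1 gene fell in pharyngeal endoderm without wild-type replicate 1 or labelled-null replicate 1, in lymphatic endothelium without labelled-null replicate 1 and in neural crest glia without wild-type replicate 3. Median and mean differed in sign for pharyngeal endoderm (0.01 and -0.15, camera lower), Notch (0.03 and -0.003, camera higher) and macrophages (-0.05 and 0.001, camera lower). In all, 14 of 27 lists passed in camera with the preset correlation, 9 higher and 5 lower, and 1, the core mesoderm regulators, passed with an estimated correlation and with fry. The same preset test called 1 to 6 lists in each of the other splits of the 6 arrays into 3 and 3. Passing it is therefore not by itself evidence of a difference between genotypes. Ttr, a yolk sac and choroid plexus transport protein counted among the endodermal markers, differed by -1.78 (SE 0.49) and passed with the replicate block (adjusted p = 0.0361), and it read 8.32 on wild-type replicate 2, the array on which yolk sac transcripts were highest.

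**Figure D4:**
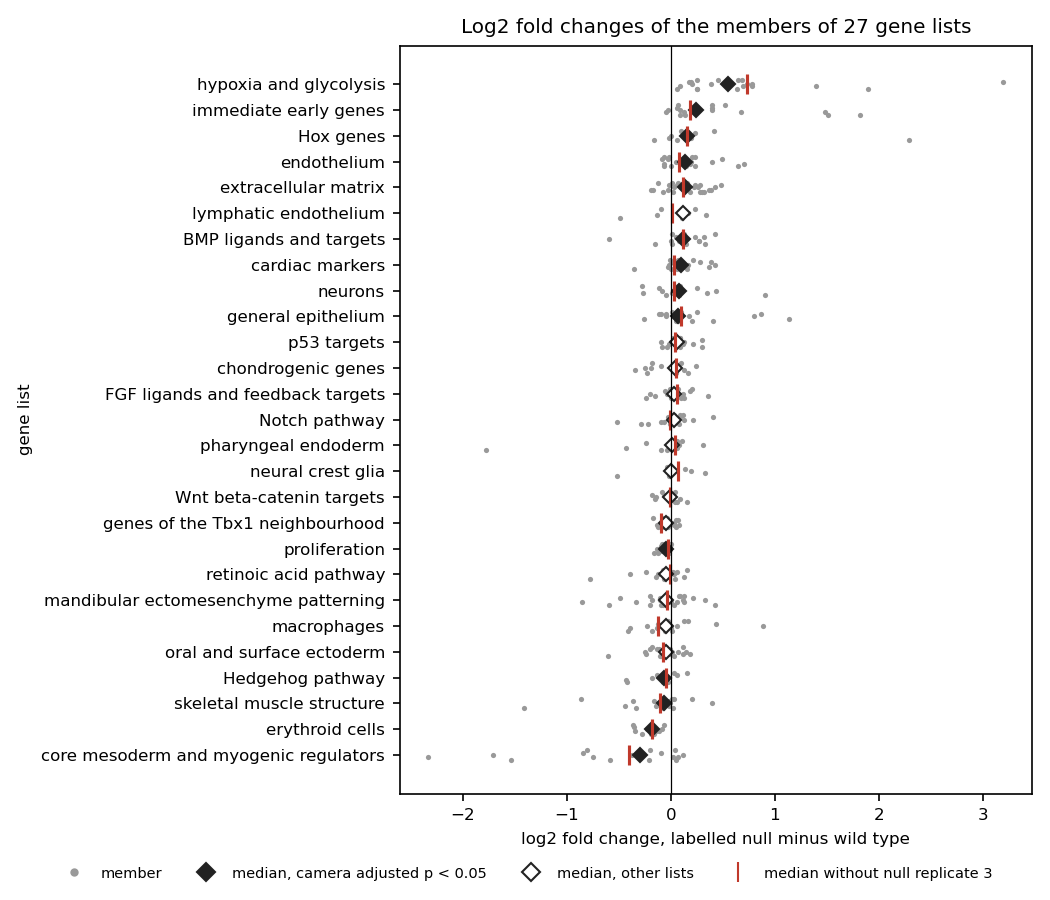
Log2 fold changes, labelled null minus wild type, of the members of 27 gene lists. Grey points are genes, diamonds list medians, filled where camera with the preset correlation gave an adjusted p under 0.05, and red bars medians without labelled-null replicate 3. Hypoxia and glycolysis genes have the highest median, 0.54, and core mesoderm and myogenic regulators the lowest, -0.29.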

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

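The estimated-correlation tests without labelled-null replicate 3 and with the replicate block, and list medians and counts over the list alone with 1 array left out, were chosen after seeing the data; the others were planned, and the cause of a change was not tested unless stated. Higher and lower genes in limma numbered 2 and 4, and 1 and 4 after a further quantile normalization or with arrays centred on their medians. They were 0 and 2 without a filter, with a floor of 4, without the trend and over single probe sets (274, 239, 270 and 469 higher at an unadjusted p under 0.05), 0 and 0 with the mean of a gene's probe sets (246 and 231 at an unadjusted p under 0.05), and 4 and 6 with a robust trend and with the replicate block. For the genes and the fixed lists the block changed no call besides those printed beside it. The integrated stress response genes described below were not tested with it as a list. The probe set with the widest interquartile range gave 10 lists past the threshold, array weights 11, and no filter or mean probe sets 12. Leaving out 1 array gave 0 to 14 higher and 0 to 8 lower genes; the lists past the threshold ranged from 11 to 15 and Tbx1 from 0.34 to 0.54. Lists past the threshold fell from 14 to 1 with an estimated correlation or fry (8 each at an unadjusted p under 0.05), and to 0 with that estimate without labelled-null replicate 3 or with the replicate block (6 and 3 in camera at an unadjusted p under 0.05).

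Lists not past the threshold turned direction, given as adjusted p: neural crest glia without a filter (0.998), with mean probe sets (0.372) and with the widest interquartile range (0.157); pharyngeal endoderm with mean probe sets (0.947) and without labelled-null replicate 3 with an estimated correlation (0.711); FGF ligands and feedback targets with the widest interquartile range (0.672); Wnt beta-catenin targets (0.744) and the retinoic acid pathway (0.746) with array weights. With 1 array left out, direction turned at least once for lymphatic endothelium (0.0822 to 0.987), FGF (0.0940 to 0.586), Wnt (0.307 to 0.924), Notch (0.433 to 0.987), the Tbx1 neighbourhood (0.00438 to 0.944), pharyngeal endoderm (0.0112 to 0.903) and Isl1 (log2 change -0.0319 to 0.198). Other settings left 492 values of single genes on the same side, with 22 weaker and 11 stronger, and 326 of lists, with 66 weaker and 3 stronger; with 1 array left out these were 266, 19 and 8 for genes and 130, 16 and 9 for lists.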

Other observations

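All tests in this part were chosen after the result was seen, except those on trophoblast and yolk sac genes and on the number of lists over splits of the arrays. The limma fit of all genes without labelled-null replicate 3 was planned too. Genes outside the rule were named after their values were seen.

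Genes of the integrated stress response, the programme run by Atf4, were mostly higher on the arrays labelled null. Of members named after their values were seen, Trib3, a pseudokinase target of Atf4, differed by 1.04 (log2, SE 0.18), Chac1, a glutathione-degrading enzyme, by 1.02 (SE 0.36) and Ddit4, an inhibitor of mTOR signalling, by 0.77 (SE 0.19), none past the threshold with all arrays; without labelled-null replicate 3 their adjusted p-values in limma were 0.0389, 0.0136 and 0.0136. The list was written after 9 of its genes had been seen to be higher, so it was tested on the 20 whose values had not been seen, a restriction made after a run on all 29 (p = 0.00539 in camera with an estimated correlation). Of the 20, 17 had higher means (median log2 change 0.18), 0 passed adjusted over the list alone in limma and 3 at an unadjusted p under 0.05, and camera gave p = 0.00567 with an estimated correlation and 0.00789 without labelled-null replicate 3. These 2 p-values are not adjusted over lists. They are also no independent test, since the pathway was chosen because 9 of its members were higher on these same arrays. Leaving those 9 out does not undo that choice. The hypoxia list, whose adjusted p did not pass, had an unadjusted p of 0.0126 in camera with an estimated correlation and all arrays. The pathway may be raised together with the hypoxia genes, a hypothesis that leaves handling of the tissue open.

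Without labelled-null replicate 3 further genes passed in limma, named after their values were seen: Eno2, a glycolytic enolase, was 5.14-fold higher (log2 2.36, SE 0.25, adjusted p = 0.0121) and Ndufa4l2, a hypoxia-inducible mitochondrial protein, 3.81-fold higher (log2 1.93, SE 0.20, adjusted p = 0.00963). Emx2, a homeobox factor, was 3.51-fold lower (log2 -1.81, SE 0.18, adjusted p = 0.00866), and Col8a2, a collagen chain, 3.66-fold lower (log2 -1.87, SE 0.24, adjusted p = 0.0235). With all arrays these 4 did not pass, and Eno2 and Ndufa4l2 had overlapping groups. The fit without that array gave Lhx2 an adjusted p of 0.00347.

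Labelled-null replicate 3 stood apart from the other arrays. Yolk sac tissue is argued against, since 19 yolk sac genes showed no excess (median -0.16, 95th percentile of matched random lists 0.10). The other arrays include wild-type replicate 2, on which these genes were raised (median excess 0.29). That lowers the value, so it is not read as a fall. Degraded RNA is argued against by a difference between 3 prime and 5 prime control probe sets of 0.753, within the 0.651 to 0.839 of the other arrays. Placental tissue in that sample is a candidate source: 37 trophoblast genes, 0 of which the fixed lists hold and 16 of which averaged above 4 on the wild-type arrays, had a median excess of 0.36 (95th percentile 0.07), and 10 lay more than 1 above the other arrays, led by Prl8a9 at 10.85 and Ctsj at 10.79. That list was written before its genes were seen except Flt1, which was then left out; with it the median was 0.23. 15 decidual and uterine immune genes had a median excess of 0.17 on this array (95th percentile 0.11) and 0.11 on labelled-null replicate 2 (95th percentile 0.07), and passed that percentile on no other array. On labelled-null replicate 2 Gzmd read 5.47 against 2.61 to 3.35 on the wild-type arrays and labelled-null replicate 1. Fits with all arrays include the sample with these placental transcripts, and fits without labelled-null replicate 3 are not known to be free of such tissue. Whether the genotype could raise these genes in the arch itself was not tested.

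The higher values of the hypoxia genes are argued against as a product of the tissue in that 1 array, since their median was 0.74 without it and 0.54 with it (0.35 without labelled-null replicate 1), and as a product of 3 prime bias, since the lowest labelled-null array lay 0.13 below the highest wild-type array (-0.13). Handling of the tissue before lysis cannot be told apart from a difference of genotype: the immediate early genes were raised over the wild-type mean by a median of 0.25, 0.08 (0.0755) and 0.26 on labelled-null replicates 1, 2 and 3, and no value here separates dissection from genotype. Fos was 8.53 and 10.38 on labelled-null replicates 1 and 3 but 7.13 on replicate 2, under the highest wild-type value of 7.39. Hspa1b, named after its values were seen, read 10.33, 7.87 and 10.29 on labelled-null replicates 1, 2 and 3, against at most 8.11 on wild type. The hypoxia median was 0.91, 0.48 and 0.23 on these arrays. Replicate 1 was above replicate 2 on Fos, Hspa1b and the hypoxia genes, and the order differed only on replicate 3, the array with placental transcripts. These ranks therefore do not decide on handling. An effect of losing Tbx1 stays open and untested.

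The size of the Hoxa2 difference stays open, since its wild-type values lie near the low end of the scale. With values under 4 raised to 4 the lowest labelled-null array lay 0.7174 above the wild-type arrays, less than the SD of 0.82 of the labelled-null arrays, and since the wild-type values had been seen to lie under 4, this decides nothing. Tissue of the second arch in the labelled-null dissections is a candidate explanation: 3 genes activated by Hoxa2 there, not seen beforehand, had a median log2 change of 0.19 (95th percentile of matched random lists 0.11), Zfp503 at 0.22, Zfp703 at 0.19 and Meox1 at 0.16, none past the threshold. Hoxa2 switched on in the mandibular arch itself would predict the same, so this test does not separate them. On all 3 genes wild-type replicate 3 read lowest of the wild-type arrays, so the rise rests in part on that array. Meox1 read 5.80 there and 6.24 and 6.54 on wild-type replicates 1 and 2, between which all labelled-null arrays lay (6.297, 6.395 and 6.389). Of the 3 genes seen beforehand, Alx4 was at 0.32, Hoxb2 at 0.17 (0.07 without wild-type replicate 3) and Meox2 at -0.51 (0.02 without labelled-null replicate 3).

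The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 2 higher and 4 lower genes against 0 in every other split (286 to 2022 genes at an unadjusted p under 0.05 in limma). It gave 14 lists, against 1 to 6 in each of the others. In each of the 3 counts 1 split, the real one, gave as many. Of the 9 other splits, 5 gave more genes at an unadjusted p under 0.05 than the real one (636 to 2022 against 430), which points to a structure of the samples; each of these 5 parts 1 pair. Of the 4 splits that part all 3 pairs, the others gave 0 genes and at most 4 lists; the remaining splits part 1 pair.

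Yolk sac genes were highest on wild-type replicate 2 (median excess 0.29, 95th percentile 0.11), with Afp at 8.94 and Apoa1 at 8.07. Of 7606 probe sets with no single gene named, 0 passed in limma and 131 had an unadjusted p under 0.05, a smaller share than the 0.05 expected without any difference.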
